A study of Macaca fascicularis with 7 samples.

How the data were processed

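Messenger RNA was measured in 7 libraries of cynomolgus monkey (Macaca fascicularis) oocytes. Germinal vesicle (GV) oocytes, which are arrested before meiosis resumes, gave 2 libraries. Metaphase II (MII) oocytes that had matured in the animal (in vivo matured, IVO) gave 2 libraries, and MII oocytes that had matured in culture (in vitro matured, IVM) gave 3. Per the labels' protocols, RNA was reverse transcribed from poly(A)-primed ends with template switching, the full-length cDNA was amplified by PCR and fragmented by tagmentation, and the libraries were sequenced with paired ends on DNA nanoballs. The labels do not say how many oocytes went into a library or whether libraries came from separate animals, so every p-value measures only the spread between these samples, which may be technical. Priming on poly(A) means that a transcript whose tail is shortened or lengthened can change its count without a change in the number of molecules.

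The authors deposited a table of raw counts per gene, with no normalization. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, Bowtie2 2.4.5, SAMtools 1.15.1, featureCounts 2.0.1 and DESeq2 (version not given in the sources used here). The order of the steps, the strand setting, the treatment of reads with several matches and the genome build are not given in the sources used here. Bowtie2 does not split a read across an intron, so reads over exon junctions can be lost or placed on intronless copies. Genes with near-identical copies or pseudogenes, overlapping genes and antisense genes are therefore uncertain. Coordinates are those of the deposited table, on its unnamed build.

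The table held 28161 usable gene rows. Lines of 3 very long genes, MACF1, NEB and TTN, were broken in the deposited table (10 lines) and were left out. A further 26 gene names had been turned into dates and stayed without a symbol. Of 11294 rows named only by a locus identifier, 5013 matched a gene identifier of a RefSeq gene table of the species, built on a telomere-to-telomere assembly, and 721 of them gained a symbol from it. That table was used for names and gene types only. In total 17562 rows had a symbol. The table held 0 rows on a mitochondrial chromosome, so the list of mitochondrially encoded mRNAs, with 0 of 13 members found, gave no result.

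Library totals ranged from 22901970 to 29245733 counts. A floor of 3 counts stood for a gene with 0 counts, which is 0.0907 to 0.161 CPM (counts scaled to a fixed library size) in a library. Intervals and floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules. CPM were computed from the deposited counts with library sizes scaled by TMM (trimmed mean of M values), except for the numbers of detected genes, which used unscaled totals. All values after ± are SDs between libraries, with n = 2 for GV, n = 2 for IVO MII and n = 3 for IVM MII.

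Differences between groups were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest with its default settings, trended dispersion, TMM scaling, filterByExpr) in R 4.3.3. All 7 libraries entered 1 fit, since groups of 2 or 3 need a shared estimate of the spread, and each of the 3 pairs of groups was compared in it. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Fold changes are log2 ratios with their standard errors (SE). A gene with 0 counts in a whole group is given as a lower bound against 3 counts in each library of that group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. Tables were read with Python 3.11.15 and pandas 2.3.3.

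Before the data were examined, 22 gene lists were fixed. They covered oocyte identity and zona pellucida, maternal effect and subcortical maternal complex, meiotic cell cycle and spindle checkpoint, mRNA decay and poly(A) control, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, cytoplasmic ribosomal proteins, glycolysis and pyruvate metabolism, antioxidant and glutathione defence, fatty acid oxidation and lipid storage, cholesterol biosynthesis, unfolded protein and heat shock response, apoptosis and p53, DNA damage checkpoint and repair, DNA methylation and histone modification, fertilisation with cortical granule and calcium release, proteasome, mitochondrial dynamics with import and translation, and early embryonic genome activation. The other 3 lists held markers of cumulus and granulosa cells, of stroma, theca and endothelium, and of blood and immune cells. The 20 lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. The rule for the genes named in the text was fixed at the same time. It took the 8 highest and 8 lowest fold changes per comparison among called genes with a symbol, at least 20 CPM in the higher group and no overlap between the libraries, up to 4 members per list with the smallest adjusted p, 13 fixed oocyte genes for IVM against IVO, and marker genes of other cell types at 5 CPM or more in any group.

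The whole procedure was tested on simulated counts drawn from the libraries' own means and spread, with 200 genes changed by 2-, 4- or 8-fold in each of 5 simulations. For IVM against IVO it recovered 0%, 10.7% and 31.2% of the genes changed 2-, 4- and 8-fold among 15614 tested genes. The values were for IVO against GV 0%, 2.39% and 21.2% among 15628, and for IVM against GV 0%, 8.66% and 40.9% among 15593. It made 0.8 false calls per simulation. Only 200 genes were changed in a simulation, while 4596 and 5949 were called in the data for IVO and IVM MII against GV. With fewer changed genes the adjusted threshold is stricter, so these rates can lie below those in the data. The proteasome list, lowered to 50% in the first simulation of each comparison only, was called in each of the 3 comparisons, and 0 of the other lists were. Simulated genes were drawn independently of each other. In the data the estimated correlation within the oxidative phosphorylation list was 0.29 for IVO MII against GV. The simulations therefore do not measure how often lists of correlated genes are called falsely.

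Alternatives chosen before the data were examined were RLE and upper quartile scaling, other filters on low counts, DESeq2 1.42.0, limma voom, robust and legacy edgeR fits, a fit of only the groups compared, replicate numbers as a block, thinning to the smallest library, leaving out ribosomal protein genes, a fold minimum, each library left out in turn, other pseudocounts, an estimated correlation between genes and the fry set test. A newer edgeR quasi-likelihood fit and the use of former gene symbols for list members were added after seeing the data.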

Results

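Counts of poly(A) RNA per gene were compared between 3 kinds of monkey oocyte: immature GV oocytes, MII oocytes matured in vivo (IVO) and MII oocytes matured in vitro (IVM). The design asks how gene expression differs between oocytes matured in culture and in the animal, and how each differs from the immature oocyte. The library totals were 23249732 and 22901970 counts for GV, 23550299 and 26343911 for IVO MII, and 24332176, 26616841 and 29245733 for IVM MII. After filtering, 16374 genes were tested, which held 99.932% to 99.974% of the counts of a library.

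GV libraries held more kinds of transcript than MII libraries. At 1 CPM or more of the unscaled library totals, 14047 ± 42.4 genes were detected in GV, 11919 ± 495 in IVO MII and 11630.7 ± 404.8 in IVM MII. The TMM factors were 1.423 and 1.382 in GV and 0.7662 to 0.9848 in MII libraries, so scaled CPM would give a narrower gap. The 10 most abundant genes took 6.71% ± 0.157 of the counts in GV, 14.9% ± 2.07 in IVO MII and 12.4% ± 2.31 in IVM MII. Across genes, the Spearman correlation of log2(CPM + 1) was 0.979 between the GV libraries, 0.918 between the IVO MII libraries and 0.936 on average between the IVM MII libraries. It averaged 0.887 between IVO and IVM MII libraries, and 0.771 between GV and either kind of MII library. The third IVM MII library correlated with the IVO MII libraries at 0.911 and 0.91, about as closely as these did with each other. With the other IVM MII libraries it correlated somewhat more closely, at 0.926 and 0.931. Genes are not independent replicates, so these values describe the libraries only. The labels place the GV libraries in another folder than all MII libraries, read here as another sequencing delivery, so delivery and group cannot be told apart in any comparison with GV.

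**Figure D1:**
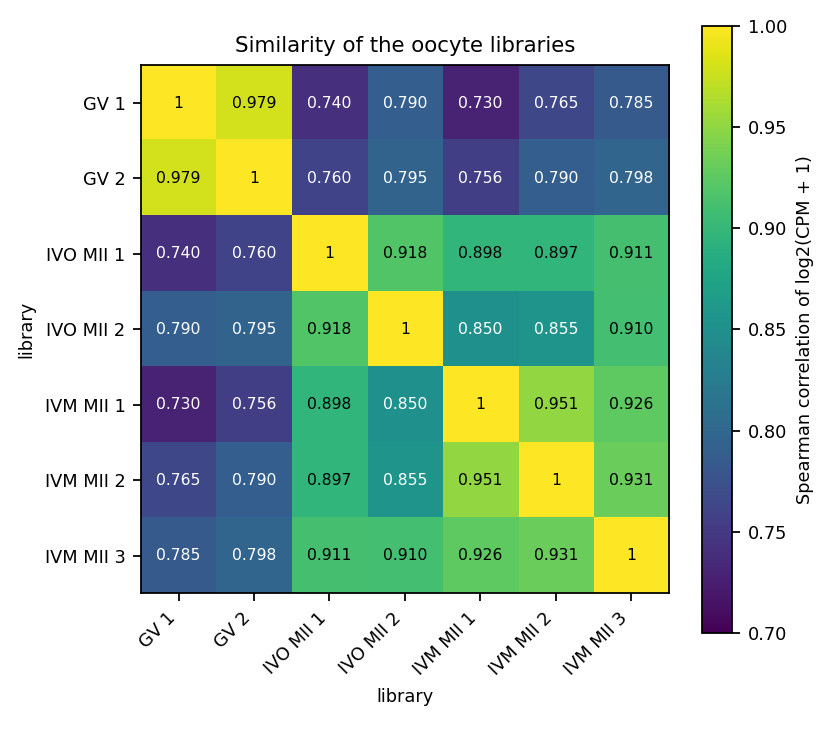
Spearman correlation of log2(CPM + 1) over the 16374 tested genes for each pair of the 7 libraries, as colour and number. The GV pair stands at 0.979, and pairs of GV with IVO or IVM MII libraries average 0.771.

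Oocytes matured in vitro and in vivo differed in 241 genes, of which 146 were higher in IVM MII and 95 were higher in IVO MII. The spread behind this test was shared with the GV libraries, which lie outside the comparison. The GV pair was closer (Spearman correlation 0.979) than the IVO MII pair (0.918). A fit of only the groups compared called 54 genes. Among the genes higher in IVM MII was CD46, which encodes a membrane regulator of complement (chromosome 1, bases 66323691 to 66361684 of the deposited table). It had 21.7 ± 5.71 CPM in IVM MII and 0 counts in both IVO MII libraries, at least 162-fold higher (edgeR adjusted p = 0.00585). ZNF711, a zinc finger gene, had 45.9 ± 22.4 CPM in IVM MII and 1 count in all IVO MII libraries, a ratio of 2090 (95% counting interval 375 to 82600). MATN3, which encodes a cartilage matrix protein, had 30.2 ± 25.9 CPM against 2 counts, a ratio of 687 (190 to 5670). FAM83D, which encodes a mitotic spindle protein (chromosome 10, bases 70544833 to 70573725), rose from 4.45 ± 1.18 CPM in IVO MII to 211 ± 92.2 in IVM MII, a log2 fold change of 5.56 (SE 0.57, edgeR adjusted p = 0.00823). Also higher in IVM MII were ART3 (log2 fold change 7.02), NKIRAS1 (5.84), the synaptonemal complex gene TEX12 (5.17) and DUSP5 (5.17), which encodes a phosphatase of ERK kinases.

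Among the genes higher in IVO MII, IGSF9 (chromosome 1, bases 91727631 to 91746623) had 29.5 ± 18.7 CPM in IVO MII and 0 counts in all 3 IVM MII libraries, at least 221-fold lower in IVM MII (edgeR adjusted p = 0.0104). The neuronal growth gene GAP43 was at 47.2 ± 33.1 CPM in IVO MII and 0.0875 ± 0.0392 in IVM MII. ANKRD22 (chromosome 9, bases 87376033 to 87404692) was at 169 ± 88.5 CPM in IVO MII and 1.44 ± 1.02 in IVM MII, a log2 fold change of -6.89 (SE 0.74, edgeR adjusted p = 0.0104). MPP4, of the membrane-associated guanylate kinases, was at 283 ± 65.3 CPM against 9.62 ± 4.01, a log2 fold change of -4.88 (SE 0.43, edgeR adjusted p = 0.00585). FAM110A (-4.63), TCEAL4 (-4.43), the calcium channel gamma subunit gene CACNG7 (-4.09) and the lipid droplet gene PLIN5 (-3.93) were lower in IVM MII as well.

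The number of genes called between IVM and IVO MII depended strongly on single libraries. It was 0 without IVM MII replicate 1 and 0 without replicate 2, where 2703 and 2549 genes had an unadjusted edgeR p under 0.05, against 3460 in the full data. It was 1277 without IVM MII replicate 3, 22 without IVO MII replicate 2, 364 without IVO MII replicate 1, 96 without GV replicate 1 and 64 without GV replicate 2. The direction moved too: without IVO MII replicate 2, 6 genes were higher and 16 lower in IVM MII, and without IVO MII replicate 1, 253 were higher and 111 lower. A fit of only the groups compared called 54 genes, DESeq2 2010, limma voom 497 and the newer edgeR fit, chosen after seeing the data, 772. None of the 24 called genes that the naming rule took kept its call without IVM MII replicate 1 or without replicate 2, where the smallest edgeR adjusted p among all genes was 0.0513 and 0.0528. In the settings in which they were tested, 0 of these 24 genes changed direction. With upper quartile scaling 127 genes were higher and 125 lower in IVM MII, so the share of higher genes moved from 60.6% to 50.4%. That scaling moved the median log2 fold change of all genes from 0 to -0.11. Among the 241 genes, 32.8% had no symbol, against 24.1% of all tested genes.

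**Figure D2:**
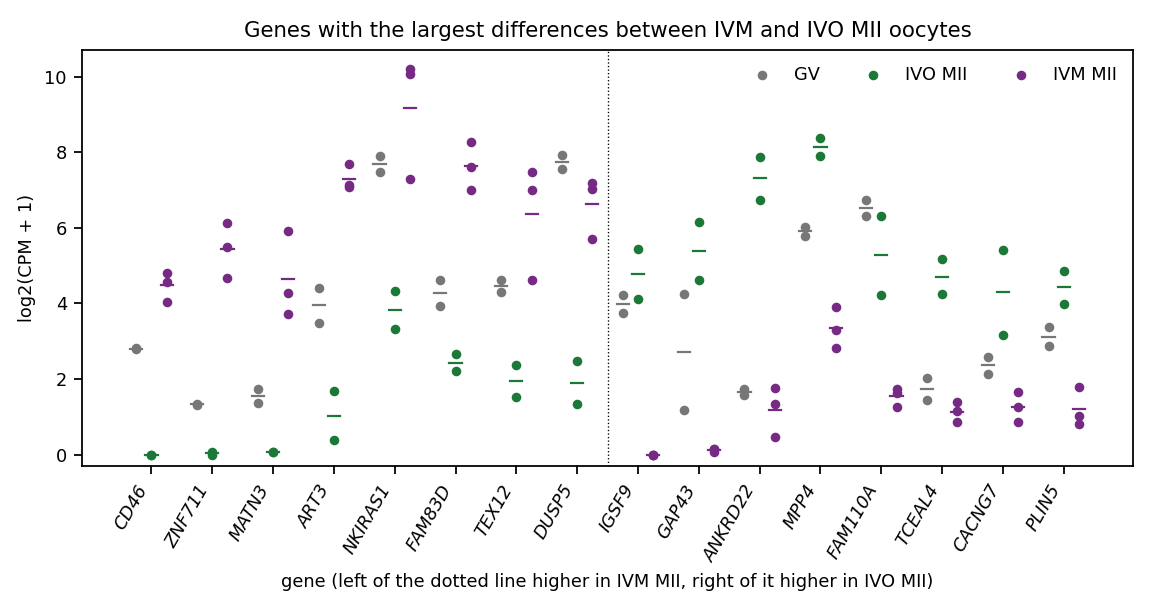
Expression, as log2(CPM + 1), of the 8 genes with the highest and the 8 with the lowest log2 fold change between IVM and IVO MII under the naming rule; each point is a library and each bar the mean of a group's log2 values. CD46 was at 0 counts in both IVO MII libraries and IGSF9 at 0 counts in all 3 IVM MII libraries.

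Of the oocyte identity and zona pellucida genes, ZP2, which encodes a zona glycoprotein that binds sperm (chromosome 20, bases 20478292 to 20492633), rose from 895 ± 202 CPM in IVO MII to 3344 ± 324 in IVM MII (log2 fold change 1.90, SE 0.31, edgeR adjusted p = 0.0303). The other 17 of 18 tested members were not called. Adjusted over the list alone, 2 rose and 1 fell. In the maternal effect list, OOEP, a member of the subcortical maternal complex, was at 2489 ± 447 CPM in IVO MII and 811 ± 182 in IVM MII (-1.62, SE 0.30, edgeR adjusted p = 0.0438). In this list 22 of 23 members were not called (2 rose and 3 fell adjusted over the list alone). In the mRNA decay list, PABPC1L, an oocyte poly(A)-binding protein gene, fell by 3.41 on the log2 scale and CNOT7, which encodes a deadenylase of the CCR4-NOT complex, fell by 1.47. Of 39 members 37 were not called (1 rose and 3 fell adjusted over the list alone). CD9, which encodes an egg surface tetraspanin with a role in sperm fusion, rose by 2.38 as the only called member of 22 tested in the fertilisation list (6 rose and 3 fell adjusted over the list alone). IDI1 of cholesterol biosynthesis rose by 2.86 (1 of 21 called; 1 rose adjusted over the list alone). The stress gene GADD45A of the apoptosis and p53 list rose by 2.34 (1 of 24 called; 2 rose adjusted over the list alone). ZNF280A of the early embryonic genome activation list fell by 5.70 from a low level (1 of 6 called; 1 rose and 1 fell adjusted over the list alone).

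Many oocyte genes fixed beforehand did not pass the test between IVM and IVO MII. The growth factor genes GDF9 and BMP15 had log2 fold changes of 0.76 (SE 0.43) and 0.04 (SE 0.34), and the zona gene ZP3 0.92 (SE 0.91). The cell cycle genes MOS, CCNB1 and WEE2 had 1.68 (SE 0.46, edgeR adjusted p = 0.0964), -0.20 (SE 0.29) and -0.87 (SE 0.49). BTG4, an adaptor of mRNA deadenylation, had 0.07 (SE 0.41), DPPA3 -0.53 (SE 0.42), NLRP5 0.65 (SE 0.57), DNMT1 0.36 (SE 0.28), SOD1 0.86 (SE 0.49) and GPX4 -0.14 (SE 0.66). In simulated data with 200 changed genes, 0% of the 2-fold changes were recovered, a rate that holds for that setting only. With SEs of 0.28 to 0.91, these values do not show that the genes were alike.

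By camera, 0 of the 20 tested lists differed between IVM and IVO MII, and 3 had an unadjusted camera p under 0.05. After adjustment fry called 0 lists, with 5 at an unadjusted fry p under 0.05, and camera with an estimated correlation called 0, with 0 at an unadjusted p under 0.05. The 3 lists were oxidative phosphorylation (median log2 fold change 0.33, 0 of 61 called), cytoplasmic ribosomal proteins (0.35, 0 of 77 called) and the unfolded protein and heat shock response (0.41, 0 of 27 called), each at an adjusted camera p of 0.28. Adjusted over the list alone, 0 of their members passed. Without IVO MII replicate 1, camera with the preset correlation of 0.01 called the first 2 of these lists higher in IVM MII. That fit rests on 1 IVO MII library. In the full data the estimated correlation was 0.27 within the first list and 0.6 within the second, so the preset overstates the evidence for both. In the antioxidant list 0 of 29 members were called, and 4 rose and 4 fell adjusted over the list alone. The lists of glycolysis, fatty acid oxidation, DNA damage, DNA methylation and proteasome had 0 called members by either adjustment. The meiotic cell cycle list had 0 of 42 called and 1 that rose adjusted over the list alone, and the mitochondrial dynamics, import and translation list had 0 of 35 called, with 1 up and 1 down adjusted over the list alone.

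Many more genes were called between IVO MII and GV than between IVM and IVO MII. Delivery and group cannot be told apart in this comparison with GV. Against GV, 2392 genes rose and 2204 fell in IVO MII. AP1AR, whose product regulates vesicle traffic (chromosome 5, bases 111590684 to 111633049), rose from 0.199 ± 0.103 to 33.9 ± 13.8 CPM (log2 fold change 7.37, SE 0.60, edgeR adjusted p = 0.0021). The integrin gene ITGAV (6.75, SE 0.92), ANKRD22 (6.29), KRT23 (5.92), ENPP2 (5.84), which encodes autotaxin, and the urea cycle gene CPS1 (5.79) also rose. FABP9 rose from 3 counts in GV, a ratio of 659 (95% counting interval 226 to 3200), with 1174 counts in IVO MII replicate 1 and 34 in replicate 2. Its edgeR adjusted p of 0.0141 became 0.159 without that library, 0.0516 and 0.0743 without GV replicates 1 and 2, and 0.118 with limma voom. The interferon-induced gene IFI35 (chromosome 16, bases 54777415 to 54786106) fell from 35.7 ± 4.91 CPM in GV to 0 counts in IVO MII, at least 266-fold lower (edgeR adjusted p = 0.00211). THEG fell to 0 counts from 27 ± 13.4 CPM, at least 201-fold lower, and CYP4V2 to 1 count from 56 ± 33.2 CPM, a ratio of 2550 (457 to 101000). The glyoxalase gene HAGH (-8.25, lost without IVO MII replicate 1 at edgeR adjusted p = 0.0598), BRMS1 (-7.63), PQBP1 (-7.35), SSSCA1 (-7.24) and NTMT1 (-7.07) fell as well.

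Transcripts of the nuclear-encoded respiratory chain lay lower in IVO MII than in GV. Of 61 tested members of the oxidative phosphorylation list, 33 fell and 1 rose (38 and 2 adjusted over the list alone), with a median log2 fold change of -2.39 and an adjusted camera p of 5.79e-08. The call was lost with an estimated correlation, at adjusted p = 0.308. UQCRC1 of complex III (chromosome 2, bases 103720830 to 103734559) fell from 163 ± 0.535 to 2.57 ± 1.33 CPM (log2 fold change -5.98, SE 0.67, edgeR adjusted p = 0.0021), CYC1 from 61.1 ± 4.18 to 1.30 ± 0.614, and the complex I genes NDUFB7 and NDUFA2 by 3.28 and 4.59 on the log2 scale. In the mitochondrial dynamics, import and translation list 15 of 35 fell and 3 rose (16 and 4 adjusted over the list alone; median -1.08, adjusted camera p = 0.00871, 0.187 with an estimated correlation), with MRPL15 at -4.19 and MRPS18B at -2.86, both of the mitochondrial ribosome.

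Transcripts of the mRNA decay and poly(A) control list rose, 18 of 39 members up and 1 down (18 and 3 adjusted over the list alone; median 1.24, adjusted camera p = 0.000105, 0.132 with an estimated correlation). The deadenylase gene CNOT6L (chromosome 5, bases 56665036 to 56767717) rose from 47.3 ± 9.01 to 335 ± 76.5 CPM (2.82, SE 0.34, edgeR adjusted p = 0.0021), CNOT7 from 103 ± 8.40 to 561 ± 74.7, the decapping gene DCP2 from 260 ± 21.5 to 1340 ± 296 and LSM14A from 13.9 ± 0.898 to 126 ± 60.4. In the DNA damage list 13 of 37 rose and 4 fell (13 and 4 adjusted over the list alone; median 0.61, adjusted camera p = 0.0324, 0.187 with an estimated correlation), with BRCA2 at 2.31.

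Other lists fell with weaker evidence. For glycolysis and pyruvate metabolism 9 of 23 fell and 2 rose (10 and 2 adjusted over the list alone; median -1.26, adjusted camera p = 0.0346, 0.187 with an estimated correlation), with TPI1 at -4.32, ENO1 at -5.45 and GAPDH at -3.83. For antioxidant defence 11 of 29 fell and 2 rose (12 and 3 adjusted over the list alone; median -1.37, adjusted camera p = 0.0346, 0.187 with an estimated correlation), with GLRX at -4.48 and the mitochondrial peroxidase gene PRDX3 up by 2.25. For the proteasome 13 of 33 fell and 2 rose (16 and 6 adjusted over the list alone; median -0.94, adjusted camera p = 0.0346, 0.205 with an estimated correlation), with PSMD8 at -5.06 and PSMC5 at -5.13. In this order, the limma camera values of these lists after adjustment became 0.0546, 0.107 and 0.107 without GV replicate 2, and 0.113, 0.297 and 0.119 without IVO MII replicate 2. Those of glycolysis and the proteasome became 0.0668 and 0.0947 without IVO MII replicate 1.

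In the lists without a camera call, members moved both ways. The meiotic cell cycle list had 9 of 42 up and 9 down (10 and 9 adjusted over the list alone). FBXO43, which encodes an inhibitor of the anaphase-promoting complex, rose from 6.94 ± 1.86 to 91.7 ± 29.9 CPM and the kinesin gene CENPE from 301 ± 34.9 to 1627 ± 170, while MOS, which encodes the kinase behind MII arrest, fell from 544 ± 183 to 32.8 ± 12.7. The maternal effect list had 8 of 23 down and 2 up by either adjustment, with NPM2 at -3.59, TLE6 at -3.45 and NLRP4 at 2.20. The oocyte identity list had 5 of 18 up and 3 down by either adjustment, with FIGLA at -3.38 and RBM46 at 2.31. DNA methylation and histone modification had 11 of 47 up and 2 down by either adjustment, with TET3 at 3.14, DNMT3B at 2.55 and DNMT3A at -2.52. The remaining lists, given as up, down and tested, were the unfolded protein and heat shock response with 4, 9 and 27 (4 and 11 adjusted over the list alone), fatty acid oxidation with 4, 6 and 26 (4 and 9). They also included cholesterol biosynthesis with 3, 2 and 21 (3 and 2), apoptosis and p53 with 3, 2 and 24 (3 and 2), fertilisation with 3, 5 and 22 (3 and 5), cytoplasmic ribosomal proteins with 9, 3 and 77 (3 and 1) and early embryonic genome activation with 1, 1 and 6 (1 and 1). Mean and median differed in sign for the meiotic, ribosomal protein, apoptosis and embryonic genome activation lists, and the median of the ribosomal protein list, -0.0021, turned positive with upper quartile scaling. The number of changed genes was 1484 without GV replicate 1, 1700 without GV replicate 2 and 3011 without IVO MII replicate 1.

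IVM MII differed from GV in 5949 genes, with 3037 up and 2912 down, where delivery and group again cannot be told apart. AP1AR rose to 73.3 ± 7.79 CPM (log2 fold change 8.48, SE 0.62, edgeR adjusted p = 0.00109) and ACVR1C to 67.6 ± 10.8 (7.31, SE 0.86). The olfactory receptor gene OR2A25 (8.19), TMSB15A (6.51), ITGAV (6.27), C7H14orf39 (6.17), FBXL17 (5.91), which encodes an F-box protein, and the transcription factor gene FOXF2 (5.86) also rose. Some of these rises were not particular to IVM MII. ACVR1C had 6 and 21 counts in GV and 1175 and 441 in IVO MII, and OR2A25 had 4 and 1 against 192 and 434. By contrast, C7H14orf39 had 15 and 17 counts in GV and 71 and 17 in IVO MII. IFI35 fell to 0 counts in all 3 IVM MII libraries, at least 267-fold lower (edgeR adjusted p = 0.00137). SERTAD1 (-9.48), CCDC63 (-7.56), TMEM177 (-7.52), CYP4V2 (-7.20), the thymidine kinase gene TK1 (-7.16), DGCR14 (-7.15) and the glutathione-degrading enzyme gene CHAC1 (-7.11) fell as well. The number of changed genes was 2110 without GV replicate 1 and 2550 without GV replicate 2.

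The oxidative phosphorylation list lay lower in IVM MII too, with 31 of 61 down and 4 up (35 and 7 adjusted over the list alone; median -1.96, adjusted camera p = 4.46e-05, 0.473 with an estimated correlation). UQCRC1 fell by 6.07, CYC1 by 5.53, NDUFB7 by 4.17 and COX8A by 4.55 on the log2 scale. For the mRNA decay list 19 of 39 rose and 4 fell (19 and 6 adjusted over the list alone; median 1.12, adjusted camera p = 0.00577, 0.169 with an estimated correlation), with CPEB2 at 4.67, CPEB4 at 2.91, CNOT6L at 2.90 and the m6A reader gene YTHDF3 at 2.68. For the proteasome 16 of 33 fell and 4 rose (16 and 5 adjusted over the list alone; median -0.96, adjusted camera p = 0.0181, 0.169 with an estimated correlation). For glycolysis 11 of 23 fell and 2 rose (12 and 3; median -1.61, 0.0181 and 0.169). For mitochondrial dynamics, import and translation 14 of 35 fell and 5 rose (15 and 5; median -0.90, 0.028 and 0.169), and for DNA damage 17 of 37 rose and 6 fell (18 and 7; median 0.72, 0.0372 and 0.169). PSMD8 stood at -5.05, GAPDH at -4.72, MRPS15 at -5.33 and CLPP at -3.21, while CHEK1 rose by 2.29 and PCNA by 1.74. The calls of the oxidative phosphorylation and mRNA decay lists held with each library left out in both maturation comparisons, though not with an estimated correlation. Within the oxidative phosphorylation list that correlation was 0.29 in both comparisons, above the preset 0.01. Within the mRNA decay list it was -0.018 in IVO MII and -0.019 in IVM MII, below the preset. A higher correlation between members thus did not cost the mRNA decay list its calls. At a mean CPM of at least 10 the mRNA decay list lost its call in IVM MII (limma camera adjusted p = 0.064) and kept it in IVO MII. The other 4 of these lists lost their calls without at least 1 library, with adjusted camera p values (limma) of up to 0.0624 for glycolysis and the proteasome, both without IVO MII replicate 2, and up to 0.0675 for the mitochondrial and DNA damage lists, both without IVM MII replicate 3.

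The antioxidant list missed the threshold in IVM MII, with 14 of 29 down and 6 up by either adjustment (limma camera adjusted p = 0.0522), and with IDH2 at -6.67 and GPX1 at -4.51. The meiotic list had 12 of 42 up and 9 down (13 and 10 adjusted over the list alone), with AURKB at -3.28, CENPE at 2.38 and KIF11 at 2.02. The maternal effect list had 3 of 23 up and 8 down (3 and 9), with FOXR1 at -3.67 and DPPA5 at -2.31, and the oocyte identity list 7 of 18 up and 3 down (7 and 4). DNA methylation and histone modification had 10 of 47 up and 3 down by either adjustment, with DNMT1 at 1.96 and KDM1B at 3.08. The remaining lists, given as up, down and tested, were the unfolded protein and heat shock response with 5, 7 and 27 (5 and 7 adjusted over the list alone), fatty acid oxidation with 2, 3 and 26 (1 and 3). They also included cholesterol biosynthesis with 5, 5 and 21 (5 and 5), apoptosis and p53 with 6, 3 and 24 (6 and 3), fertilisation with 6, 3 and 22 (7 and 4), cytoplasmic ribosomal proteins with 11, 3 and 77 (3 and 1) and early embryonic genome activation with 1, 1 and 6 (1 and 2). Mean and median differed in sign for the maternal effect, apoptosis and fertilisation lists, and the medians of the maternal effect and oocyte identity lists, 0.0039 and 0.14, turned negative with RLE scaling.

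**Figure D3:**
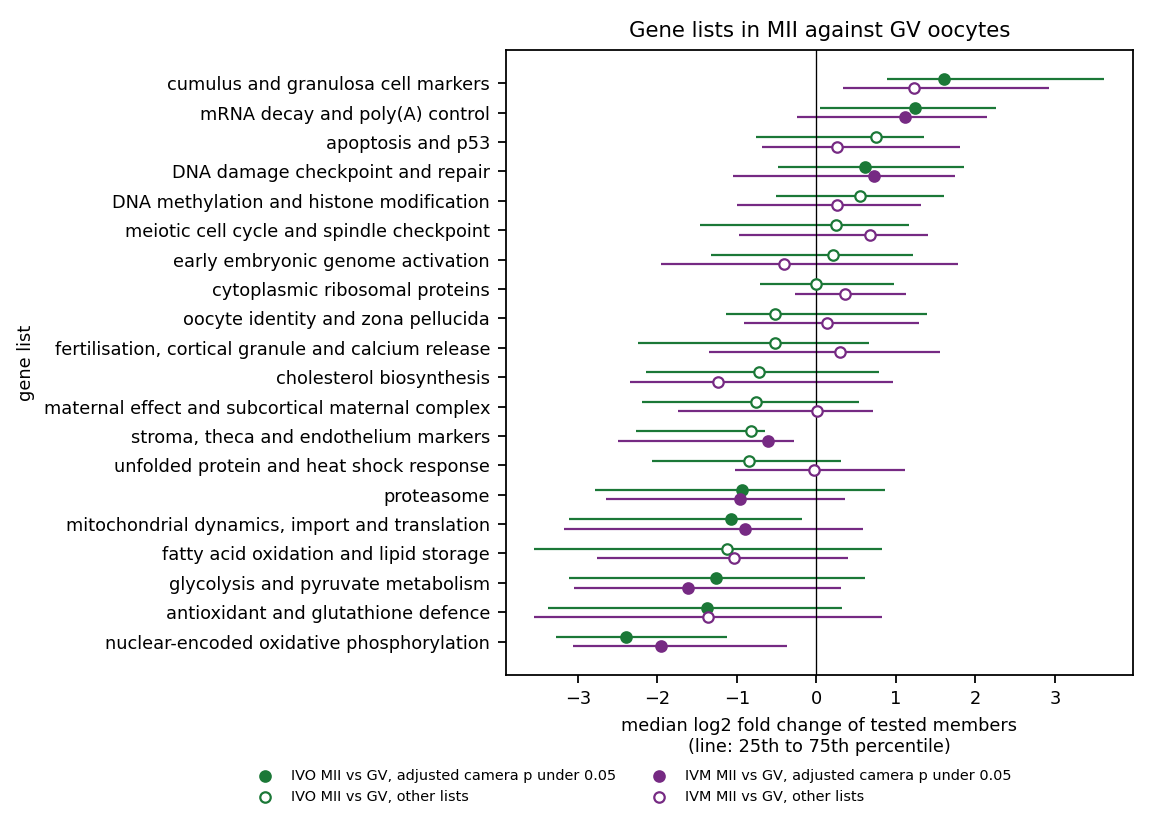
Median log2 fold change of the tested members of each list with at least 5 tested members, for IVO MII and IVM MII against GV; lines span the 25th to 75th percentile and filled points mark an adjusted camera p under 0.05. The oxidative phosphorylation list stands at -2.39 and -1.96.

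The balance of genes up and down against GV depended on the scaling. With RLE scaling 2156 genes rose and 2391 fell in IVO MII, and 2677 rose and 3247 fell in IVM MII, so more genes fell than rose. With upper quartile scaling the numbers were 2398 and 2189 in IVO MII, and 2767 and 3093 in IVM MII. The median log2 fold change of all genes was -0.16 in IVO MII and -0.099 in IVM MII with TMM, and -0.26 and -0.24 with RLE scaling. Each change above is thus relative to a centre that moves by about that difference between these scalings. Each scaling is itself relative, so a change in the total mRNA of an oocyte would show in none of them. The difference between scalings therefore does not bound that error, and the rises above are relative rises. The lists called by camera kept the sign of their medians under TMM, RLE and upper quartile scaling.

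Both comparisons with GV called many of the same genes. In the same direction in both, 1962 genes rose and 1559 fell, where independent lists of these sizes would share 443.66 and 391.97, and 22 genes were called in opposite directions. Fold changes correlated at 0.709 across genes, against 0.546 in 20 simulations of unchanged groups compared with the same GV libraries, and their covariance was 4.51 against 0.576 simulated, a difference of 3.933. The simulated groups had at most 2 called genes in a direction, so their 0 shared calls say nothing about sharing among real calls. In a comparison chosen after this result was seen, group means of log2(CPM + 1) were taken less GV. Changes in IVO and IVM MII then correlated at 0.83 with both GV libraries on both sides, and at 0.82 and 0.777 with IVO MII taken against one GV library and IVM MII against the other. Both GV libraries lie in the same folder, so a bias common to them remains. Calls were not repeated on split controls, which would leave 1 GV library on each side, so part of the excess of shared calls may come from the shared controls. The number of shared calls, 3521, was 1078 without GV replicate 1 and 1327 without GV replicate 2.

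Genes that differed between IVM and IVO MII differed from GV in both directions. They were chosen by a test on the same IVO and IVM MII libraries, which favours opposite directions against GV in the counts below. Of the 146 genes higher in IVM MII, 85 were lower and 3 higher in IVO MII than in GV, and 70 were higher and 12 lower in IVM MII than in GV. Of the 95 genes lower in IVM MII, 40 were higher and 8 lower in IVO MII than in GV, and 62 were lower and 7 higher in IVM MII than in GV. DUSP5, for example, was at 216 ± 38.2 CPM in GV, 3.02 ± 2.14 in IVO MII and 108 ± 50.1 in IVM MII, and ANKRD22 was at 2.15 ± 0.221, 169 ± 88.5 and 1.44 ± 1.02.

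**Figure D4:**
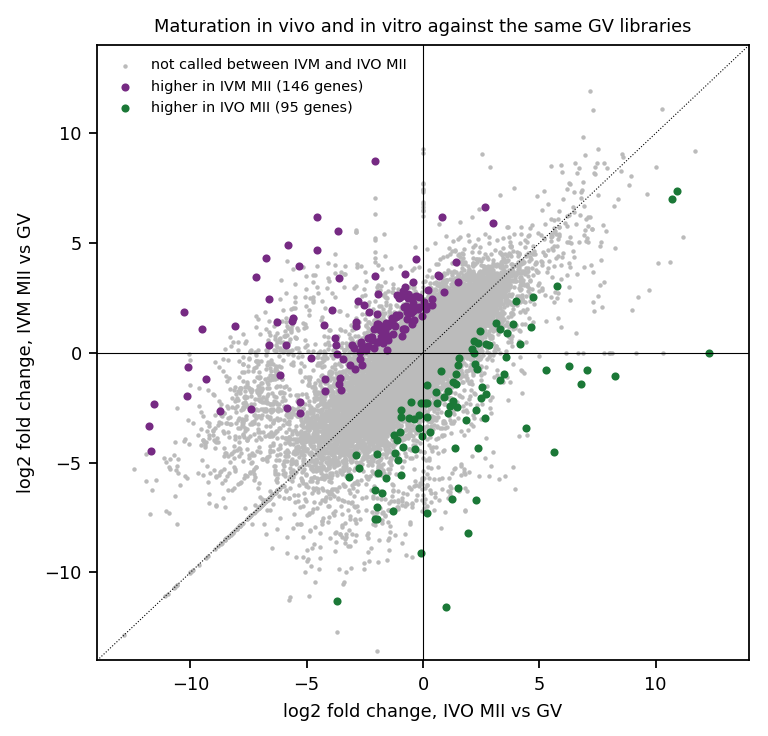
Fitted log2 fold change against GV of each tested gene in IVO MII (horizontal) and IVM MII (vertical), with the 146 genes higher in IVM MII and the 95 higher in IVO MII coloured and equality as a dotted line. Fitted values of genes at 0 counts in a group depend on the fit and are no bounds, and both axes share the 2 GV libraries.

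Markers of neighbouring cell types were mostly low, with exceptions, and some moved with the groups. The cumulus and granulosa cell marker SERPINE2 had 8776 and 2537 counts in the GV libraries, 2322 and 4690 in IVO MII, and 2679, 5060 and 10438 in IVM MII. CYP19A1 had 17 and 6 counts in GV, 193 and 32 in IVO MII and 0 in each IVM MII library. Carry-over of other cells was not tested. Of 13 tested cumulus and granulosa cell markers, 2 rose in IVO MII against GV and 0 fell (2 and 0 adjusted over the list alone; median 1.61, adjusted camera p = 0.0413, 0.205 with an estimated correlation, and 0.118 without IVO MII replicate 1 or 0.0546 without GV replicate 2). HAS2, which encodes hyaluronan synthase, rose from 6.07 ± 2.67 to 39 ± 0.625 CPM in IVO MII (edgeR adjusted p = 0.0075, 0.0803 without GV replicate 2). In IVM MII 2 rose and 1 fell (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.0958), with the FSH receptor gene FSHR rising from 1.63 ± 0.823 to 35.2 ± 16.4 CPM and TNFAIP6 from 10.5 ± 4.68 to 107 ± 47.3. Between IVM and IVO MII 0 of the 13 were called, and 1 rose and 2 fell adjusted over the list alone. Of 5 tested stroma, theca and endothelium markers, 1 fell in IVO MII and 2 in IVM MII, by either adjustment (IVM MII median -0.61, adjusted camera p = 0.0342, 0.169 with an estimated correlation, and up to 0.155 with a library left out). These were the endothelial genes VWF, at 1066 ± 105 CPM in GV (chromosome 11, bases 6156098 to 6343620), 48.5 ± 4.94 in IVO MII and 41.5 ± 4.50 in IVM MII, and CDH5, at 67 ± 11.9, 42.6 ± 18.8 and 11.9 ± 1.81 CPM, which fell in IVM MII only by this test. Between IVM and IVO MII 0 of these 5 were called, and 1 fell adjusted over the list alone. Of the blood and immune cell markers 3 were tested, too few for a set test, and 1 fell, in IVM MII against GV, by either adjustment.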

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

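The tests of scaling and of sequencing delivery below were chosen only after the results they bear on were seen. The 8 genes given here were picked out because the change with maturation differed between IVM and IVO MII by the direct edgeR test of that difference, among the genes named for the maturation comparisons. No single library was tested as an outlier, for which groups of 2 or 3 libraries give little basis.

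ANKRD22 differed by -6.893 on the log2 scale, rising by 6.29 against GV in IVO MII and standing at -0.60 in IVM MII. CCDC63 differed by -5.587, at -1.97 in IVO MII and -7.56 in IVM MII. ZNF280A differed by -5.695, at 1.37 and -4.33. CNOT7 differed by -1.47, at 2.44 and 0.97. FBXL17 differed by 2.922, at 2.99 and 5.91. IDI1 differed by 2.858, at -0.29 and 2.57. CD9 differed by 2.376, at -1.69 and 0.69. GADD45A differed by 2.339, at -0.54 and 1.80, with an edgeR adjusted p of 0.0497 for the difference. Without IVM MII replicate 1, and without replicate 2, 0 of these differences passed the test, since edgeR then called 0 genes, while 2703 and 2549 genes had an unadjusted p under 0.05. The fitted differences themselves stayed of similar size: without replicates 1 and 2 in turn they were -7.48 and -6.95 for ANKRD22, -6.16 and -5.11 for ZNF280A, -1.51 and -1.42 for CNOT7, 2.65 and 2.77 for IDI1, 2.425 and 2.29 for CD9, and 2.37 and 2.04 for GADD45A. Those of CCDC63 and FBXL17 are not given for these settings.

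Genes higher in IVM MII than in IVO MII lay mostly lower in IVO MII than in GV, which may reflect less removal of maternal transcripts in culture, or the use of the same IVO MII libraries on both sides. Against GV these 146 genes had a median log2 fold change of -1.93 in IVO MII and 1.31 in IVM MII. In IVM MII 70 of them were called higher than in GV and 12 lower. Less removal alone would not raise a transcript above GV in absolute amount, but these counts are relative. The genes were also chosen for high values in the same IVM MII libraries, which favours values above GV. The IVM MII libraries were not split to test this, so the 70 and 12 genes do not weigh against less removal. To separate less removal from the use of shared libraries, genes were called against a single IVO MII library and read in the other. Each such fit took its spread from the other groups alone. The median difference from GV in the other library was -2.61 for the 6 genes called against replicate 1 and 0.0259 for the 253 called against replicate 2, so the 2 ways disagree and the question stays open. The 10 splits of the 5 MII libraries into 3 and 2 are too few for a share under 0.05: the real split gave 241 genes, as many were given by 1 split, the real one, and the highest other, which placed IVM MII replicate 3 with the IVO MII libraries, gave 64. A difference between maturation in vivo and in vitro stays among the open explanations.

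Oxidative phosphorylation transcripts lay lower in both kinds of MII oocyte than in GV, though the camera calls were lost with an estimated correlation (limma camera adjusted p = 0.308 in IVO MII and 0.473 in IVM MII). These transcripts are short (median 816 bases, against 2964 over all tested genes). The medians of 10000 random lists matched on length and expression centred on -0.421 in IVO MII and -0.203 in IVM MII. Their 2.5th percentiles were -0.979 and -0.737, above the list's medians of -2.49 and -2.07 with former gene symbols included. Genes of like length thus fell less, which argues against gene length as the whole cause. Matched genes were drawn independently, while the estimated correlation within the list was 0.29. The percentiles are therefore too narrow for correlated genes. The ribosomal protein list, not called by camera, lay at the 97.5th and 99.2nd percentiles of its own matched lists. Scaling moves all genes of a library alike and so leaves no gap between a list and all genes. The median of the oxidative phosphorylation list less that of all genes was -1.95 or lower, which argues against scaling as the cause of the whole fall. For the same reason the gap hardly moves between TMM, RLE and upper quartile scaling, so these are not separate tests of it. The delivery of the GV libraries cannot be told apart from the group, since 0 GV libraries lie in the delivery of the MII libraries. Loss or tail shortening of these transcripts during maturation is a candidate explanation that poly(A)-primed counts alone cannot decide.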

How the results depend on the processing

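The newer edgeR fit and the former gene symbols were chosen after seeing the data. The planned legacy edgeR fit was the installed default and so gave the values already reported. For IVM against IVO MII, the 241 changed genes became 731 with no filter on low counts, 2010 with DESeq2 (240 of the 241 kept), 497 with limma voom (225 kept), 54 with only the groups compared (52 kept) and 772 with the newer edgeR fit (237 kept). RLE and upper quartile scaling, a mean CPM of at least 10, the robust fit, thinning, ribosomal protein genes left out and a 2-fold minimum gave 217 to 311. With each library left out the count ranged from 0 to 1277. The cause was not tested. For IVO MII against GV the same alternatives gave 3581 to 6313 genes and for IVM MII against GV 3997 to 7710, while with a library left out they ranged from 1484 to 5517 and from 2110 to 6716. Shared maturation calls were 2796 to 4902, and 1078 to 3797 with a library left out.

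The 0 lists called between IVM and IVO MII stayed 0 under each alternative run for the lists except without IVO MII replicate 1, where 2 lists were called. DESeq2, limma voom, the robust and newer edgeR fits and the fold minimum were not run for the lists. The 8 lists called in IVO MII against GV became 4 with no filter, 3 at a mean CPM of at least 10 and 0 with an estimated correlation (5 had an unadjusted p under 0.05 in that test; fry called 12), and ranged from 4 to 8 with a library left out. The 7 lists called in IVM MII against GV became 2 at a mean CPM of at least 10 (mRNA decay among those lost), 0 with an estimated correlation (4 had an unadjusted p under 0.05 in that test) and 12 with fry, and ranged from 3 to 7 with a library left out. Fewer tested genes go with the stricter filter, and the other causes were not tested.

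Replicate numbers were not taken to pair the samples, since the labels name no shared animal or day and groups share at most 2 numbers. Deviations of same-numbered IVM and IVO MII libraries correlated at 0.353 and -0.177 by title number and at 0.353 and 0.406 by file number, which 2 pairs leave open. Those against GV correlated at -0.234 to 0.11. With the title number as a replicate block 1238 genes were changed between IVM and IVO MII, with 5 lists called in IVO MII and 3 in IVM MII against GV. With the file number as a replicate block the values were 832 genes, 3 lists and 4 lists.

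The mean Pearson correlation of IVO with IVM MII libraries, 0.91, was 0.878 with a pseudocount of 0.1 and 0.825 over genes at a mean CPM of at least 10. That of GV with IVO MII, 0.785, was 0.762 and 0.494, and that of GV with IVM MII, 0.787, was 0.497 over the abundant genes. The mean Spearman correlations over the abundant genes were 0.807, 0.453 and 0.457 in the same order. Of the named called genes, 0 of 24 for IVM against IVO, 62 of 88 for IVO against GV and 75 of 91 for IVM against GV kept their call in each of 20 settings in which they were tested, and 0 reversed. Depth limits the genes with few counts, whose ratios have the wide intervals given above.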

Other observations

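The alternative with former gene symbols was chosen after the data were seen; the test of alignment without splicing was not. The most abundant transcripts of the MII libraries included oocyte and cell cycle genes. DPPA3, a maternal effect gene, was at 2997 ± 379.9 CPM in GV, 13590 ± 5636 in IVO MII and 9440 ± 4114 in IVM MII. BTG4 was at 1930 ± 275.3, 9316 ± 5195 and 9802 ± 2495 CPM. CKS1B, which encodes a cyclin-dependent kinase subunit, ranged over 2310 and 3220 CPM in the GV libraries, 6859 and 2428 in IVO MII, and 22780, 12860 and 11260 in IVM MII. The ubiquitin gene UBB was at 7821 and 8661 CPM in GV, 7755 and 11840 in IVO MII, and 4557, 3059 and 3583 in IVM MII. The securin family gene PTTG2 and the single-exon pseudogene LOC102116071 had close values in each library, for example 15650 and 14090 CPM in IVO MII replicate 1 and 18590 and 17710 in IVM MII replicate 1, so reads shared between copies cannot be assigned with certainty.

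When list members were also looked up by their former symbols, the oxidative phosphorylation list grew from 61 to 75 tested members, of which 42 fell and 2 rose in IVO MII against GV, and 40 fell and 5 rose in IVM MII.

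Cytoplasmic ribosomal protein genes held few of the counts, 0.234% ± 0.0286 in GV, 0.17% ± 0.0567 in IVO MII and 0.201% ± 0.0208 in IVM MII. A candidate explanation is alignment that does not split reads across introns, since the median longest exon of these 77 genes was 203 bases, against 1335 over all tested genes. Across them, mean CPM correlated with the longest exon at a Spearman rho of 0.254 (95% bootstrap interval 0.00133 to 0.465, permutation p = 0.0267, 1 relation tested), between the values set beforehand for and against this explanation, so it stays open. Genes are not independent replicates. Pseudogenes took 5.31% to 6.61% and single-exon genes 9.31% to 13.3% of the counts of a library. No biological explanation was tested.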
